A study of Homo sapiens with 4 samples.

How the data were processed

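The study covers 4 iCLIP libraries of HEK293F cells, a MOV10 pull-down and a control pull-down in each of 2 experiments, with 2 libraries a group. Per the labels' protocols, a published iCLIP procedure was used with shrimp alkaline phosphatase, the control antibody was raised against zebra finch FMRP, each library had its own barcode in the reverse transcription primer, and sequencing was on a HiSeq2000. Per the submitters' processing notes, CASAVA 1.8.2, Novoalign, SAMtools and bedtools were used with build hg19. The order of these tools, the rule that called regions and any use of the control reads are not given in the sources used here.

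The deposited files were 2 lists of aligned reads, 1 for each experiment, and 1 list of regions. That each line of the read lists is an aligned read was inferred from unique line names and widths of 17 to 91 nt. The deposited score of a read is a whole number from 0 to 70 and was read as its mapping quality, which is an inference from the values. It is not an enrichment. Read names end in 2 numbers, which were read as a copy number of a sequence and its rank. Within each group of names, copy numbers never rose with rank (0 breaks of order in each), and names were not shared between experiments. The labels tie each read list to both pull-downs of its experiment, so no test of enrichment over control was run. Of the 1181 regions, 1176 had the exact limits of the merged reads of both experiments. Positions are 1-based on hg19.

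Each read fell in a listed region, and regions were compared by their reads, by distinct fragments (reads with the same ends counted once) and by summed copy numbers. Median mapping quality was 70 in experiment 1 and 66 in experiment 2, and 14.8% and 18.9% of reads lay under 30. Reads per region were correlated over 100000 random pairings. Shares of reads were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 1181 regions. Reads that are copies of a molecule with sequencing errors are not independent, and reads with the same ends in several groups of names may not be either. Distinct fragments with nearby ends may also be variants of 1 molecule. These p-values can thus be too small. Chromosome counts were tested by exact binomial tests against 19927 protein-coding genes of GENCODE release 29. That annotation is of another build, so its gene numbers per chromosome and summed exon lengths were used and none of its positions.

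Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with a random seed of 1. The test of shares was checked on simulated data for the comparison of experiments over 1181 regions. Simulated reads were drawn independently of each other, so the check does not cover repeated counting of a molecule. With no change the test made 0 calls. With shares exchanged among 200 regions, it recovered 72 of them with 0 false calls. It recovered 61 of the 72 with at least an 8-fold change, and all 50 of those that also had 20 expected reads. Where changes in 200 regions moved the share of the other 981 to 0.659 of its value, it recovered 33 of the 200, and called 5 of the other 981. Those recovered included 4 of the 102 with at least an 8-fold change in share. Of these 102, 0 had 20 expected reads, so this count is not comparable with the 50 above. All of 300 planted pairs of fragments 1 nt apart were found.

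The named regions follow a rule fixed before the data were examined. Genes, or regions where genes cannot be named, are ranked by the lower of the best scores in the 2 experiments and then by width, with ties broken here by position, and the first 25 are named. The rule assumed a score of enrichment, and here the score is the mapping quality. Gene lists, motifs, transcript parts, base composition and cell type markers had been chosen beforehand, and were not analysed here for want of an hg19 annotation and sequence. Alternatives covered mapping quality, overlap, the unit counted, the group of read names and the totals.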

Results

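RNA bound by the helicase MOV10 was sampled by iCLIP in HEK293F cells, a human embryonic kidney line that grows in suspension. In iCLIP, UV light links protein to RNA, the complex is pulled down, and reverse transcription tends to stop at the linked base, so the 5' end of a read lies beside that base. The labels give 4 libraries, a MOV10 pull-down and a control pull-down with an irrelevant antibody in each of 2 experiments. The deposited files held 4021 aligned reads for experiment 1 and 6032 for experiment 2, and a list of 1181 regions on hg19. The labels tie each read file to both pull-downs of its experiment, and no column gives the pull-down of a read. The reads may thus be of the MOV10 libraries alone or of both, and every value below holds for the file, not for a pull-down. These reads are those inside the listed regions and do not give library depth. Per the labels, the experiments are replicates 1 and 2 of the same pull-downs, so differences between them are differences between replicates and not between conditions. All intervals cover counting error alone.

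The first question was where RNA was recovered. The 1181 regions had a median width of 38 nt (interquartile range 30 to 52, range 17 to 166) and covered 51566 nt in total. Reads lay on the plus strand in 617 regions and on the minus strand in 564, and no region held reads on both. Chromosome 17 held 127 regions against 70.3 expected from its number of protein-coding genes, a ratio of 1.81 (95% exact Clopper-Pearson interval 1.52 to 2.13, two-sided exact binomial test, adjusted p = 5.67e-09 over 24 chromosomes). Chromosome 11 held 46 regions, 0.593 of expectation (interval 0.436 to 0.786, exact test, adjusted p = 0.0012). Chromosome 8 held 23 regions, 0.568 of expectation (interval 0.361 to 0.848, exact test, adjusted p = 0.0306). Chromosome 22, with 40 regions and a ratio of 1.53 (interval 1.10 to 2.07), did not pass (exact test, adjusted p = 0.0589), but did so against exonic length (exact test, adjusted p = 0.0218) and with reads of mapping quality 30 or more (exact test, adjusted p = 0.00605), and not with 37 loci of regions up to 1000 nt apart (exact test, adjusted p = 0.0748). By such loci, chromosomes 17, 11 and 8 had ratios of 1.64, 0.621 and 0.541 (exact test, adjusted p = 2.85e-05, 0.00671 and 0.0259). The comparison with gene number was chosen after the files had been examined. It takes no account of which genes HEK293F cells express, nor of how many copies of each chromosome they hold.

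**Figure D1:**
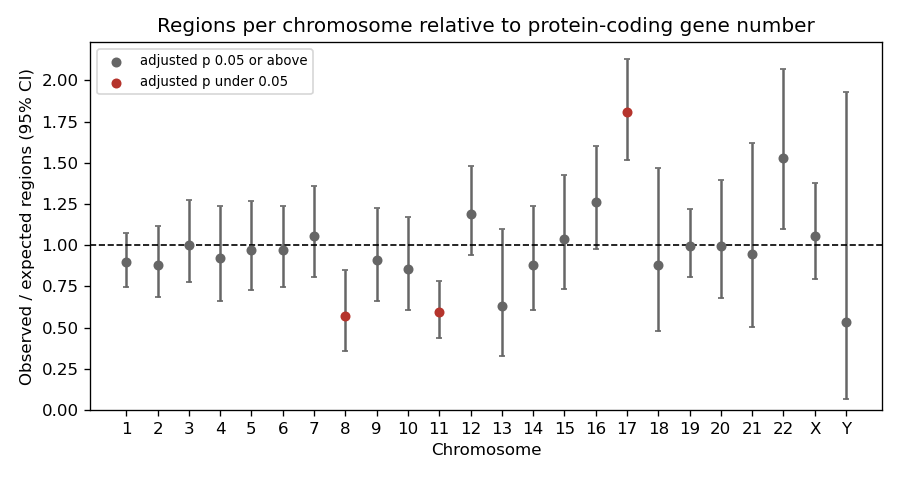
Regions per chromosome divided by the number expected from protein-coding genes (y axis, ratio), for 24 chromosomes (x axis). Points are ratios and bars are 95% exact intervals. Chromosome 17 lies at 1.81, and chromosomes 11 and 8 lie at 0.593 and 0.568.

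Some regions lay close together on the same strand. With gaps of up to 1000 nt joined, the 1181 regions formed 1079 loci, of which 69 held at least 2 regions and together 171 regions. The locus with most regions was on the plus strand of chromosome 17, from 47128694 to 47133445, with 9 regions in 4752 nt. It held 100 reads in experiment 1 and 22 in experiment 2. The next, on the minus strand of chromosome X from 73063980 to 73067636, held 7 regions in 3657 nt, with 22 reads in experiment 1 and 360 in experiment 2. In it, the regions from 73064448 to 73064476 and from 73067600 to 73067636 held 236 and 119 of the reads of experiment 2, and the other 5 regions held 19 reads in experiment 1 and 5 in experiment 2. These loci were singled out after their values were seen. Genes and transcript parts are not given, because the annotation used here is of another genome build.

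The 25 regions named here by position follow a rule fixed before the data were examined, which ranked by the deposited score and then by width. That rule assumed a score of enrichment, whereas the score in the files was read as mapping quality. Since 688 regions tie at 70 in both experiments, the choice is by width, and ties in width were broken by position, so that other regions of 92 nt and the same score are not named. They were 92 to 166 nt wide and held a median of 8 reads in experiment 1 and 2 in experiment 2. Experiment 1 had more reads in 18 of them, experiment 2 in 6, and 1 had equal numbers. Outside the 20 regions with at least 50 reads in either experiment, experiment 1 also had more reads in total, 3587 against 2552. By reads, the share differed in 11 of the 25 named regions (Fisher's exact test, adjusted p under 0.05), 3 of them higher in experiment 2. Over all 1181 regions, 54 differed. Region limits follow the merged reads, so a choice by width favours regions with many reads, where the test can detect more. By distinct fragments, only the named region of chromosome 17 from 79826025 to 79826131 passed (2 and 33 fragments, Fisher's exact test, adjusted p = 4.52e-06). The widest named region, on the plus strand of chromosome 16 from 29822099 to 29822264, held 8 reads in experiment 1 and 78 in experiment 2, or 4 and 10 distinct fragments. Its difference in share passed by reads (Fisher's exact test, adjusted p = 1.38e-08) but not by distinct fragments (Fisher's exact test, adjusted p = 1). Its median mapping quality was 70 in experiment 1 and 9 in experiment 2, since the rule uses the best read of a region. A second region on that strand, from 29821891 to 29821990, held 8 and 4 reads. On chromosome 12, the region from 20704373 to 20704498 held 80 and 36 reads with median mapping qualities of 53 and 8.5, and that from 133298053 to 133298158 held 13 and 2. The other 2 of the set on that chromosome, from 50156854 to 50156968 and from 127650875 to 127650973, held 7 and 1 and 9 and 1 reads. On chromosome 17, the regions from 47131109 to 47131202 and from 47131979 to 47132071 belong to the locus of 9 regions and held 22 and 10 and 15 and 3 reads. The region of chromosome 17 from 41167202 to 41167314 held 15 and 2 reads, that from 34069663 to 34069769 held 1 and 24, and that from 79826025 to 79826131 held 4 and 203.

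Of the remaining 14 named regions, 3 lay on chromosome X. The one from 47088943 to 47089087 held 12 reads in experiment 1 and 4 in experiment 2, that from 73062081 to 73062174 held 13 and 1, and that from 73063980 to 73064072 held 8 and 1. On chromosome 19, the region from 1577168 to 1577275 held 10 and 1 reads and that from 1587919 to 1588017 held 5 and 8. On chromosome 1, the region from 36067672 to 36067766 held 8 and 5 reads and that from 26144402 to 26144499 held 4 and 1. The regions of chromosome 1 from 984623 to 984714 and from 22396349 to 22396440 each held 1 and 2 reads. On chromosome 2, the regions from 37331628 to 37331745 and from 135209046 to 135209147 each held 4 and 1 reads. The region of chromosome 15 from 64710802 to 64710896 held 6 and 1 reads, that of chromosome 7 from 141177589 to 141177683 held 6 and 3, and that of chromosome 22 from 38616534 to 38616631 held 1 in each experiment.

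The second question was how far the 2 experiments matched. Reads of each experiment merged into 1186 clusters, and all 1186 of experiment 1 were overlapped by a cluster of experiment 2. The listed regions all hold reads of both experiments, so this overlap is a property of the list and was not tested against chance. With at least 50% of both clusters shared, 1107 clusters (93.3%) matched. As described below, 1019 of the 1181 regions held fragments with nearly the same ends in both experiments, so this overlap was largely given. Whether those fragments are independent between experiments is not settled, so the 93.3% does not measure agreement of replicates. Median mapping quality per region correlated between experiments (Pearson r = 0.83, Spearman rho = 0.82 across 1181 regions, permutation p = 1e-05 for each, the smallest that 100000 pairings can give). Regions are not independent replicates, and both experiments align to the same sequence.

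The number of reads per region correlated weakly between the experiments. Across the 1181 regions, Spearman's rho was 0.169 (permutation p = 1e-05, adjusted p = 2e-05 over 8 settings) and Pearson's r of log2 reads was 0.186 (permutation p = 1e-05). Within each of the 3 groups of reads told apart by the start of their names, taken here as sequencing runs, rho was 0.0956 (permutation p = 0.0576, 396 regions), 0.109 (permutation p = 0.0173, 489 regions) and 0.182 (permutation p = 0.00021, 415 regions), and Pearson's r of log2 reads was 0.191, 0.192 and 0.282 (permutation p = 0.00066, 0.00031 and 1e-05). In the 162 regions with no fragments of matching ends in both experiments, rho was 0.0209 (permutation p = 0.79) and Pearson's r was 0.149 (permutation p = 0.0585). Between these groups of reads within an experiment, over all 1181 regions and with empty ones included, rho was 0.28, 0.275 and 0.234 in experiment 1 (permutation p = 1e-05 for each) and 0.0667, 0.0572 and 0.0076 in experiment 2 (permutation p = 0.0228, 0.0486 and 0.794). The value between experiments lay below those within experiment 1 and above those within experiment 2, but it rests on all groups of reads and no empty regions, so these values are not directly comparable. The median region held 2 reads in experiment 1 and 1 in experiment 2, 207 regions rested on 1 read in each, and 800 rested on 1 distinct fragment in each.

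A small set of regions took 57.1% of the reads of experiment 2. Its 19 regions with at least 50 reads held 3444 of 6032 reads, and the 2 such regions of experiment 1 held 8.85% of its reads. The same regions held 16.7% and 2.6% of distinct fragments, and 92% and 57.4% of copies. The share of reads differed between experiments in 54 regions (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05), 25 with a higher share in experiment 2 and 29 in experiment 1. All 20 regions of at least 50 reads in either experiment were among the 54, and 18 of these 20 were higher in experiment 2. With them left out of the test and the totals, 14 differed, 7 in each direction. Shares add up to a whole, so the many reads of these regions in experiment 2 lower every other share there. Most of the 29 regions called higher in experiment 1 were thus not called with the reduced totals. Within the 3 groups of read names, which hold fewer reads, 8, 6 and 6 regions were higher in experiment 1. Of the distinct fragments, 53.3% in experiment 1 and 39.1% in experiment 2 occurred in at least 2 of these groups. Each of those counts as several reads in the test over all groups. The test compares these 2 sets of reads, not MOV10 with control. On the minus strand of chromosome 8, from 70602300 to 70602430, 24 reads of experiment 1 (0.597%, exact interval 0.383 to 0.887) stood against 539 of experiment 2 (8.94%, interval 8.23 to 9.68), a log2 ratio of shares of 3.90 (adjusted p = 2.57e-88). The median mapping quality of that region was 26 in experiment 1 and 29 in experiment 2. Chromosome 20 from 4760925 to 4760972 held 3 and 278 reads (log2 ratio 5.95), and chromosome 2 from 178087376 to 178087437 held 3 and 251 (log2 ratio 5.80). On chromosome 20, the best mapping quality in experiment 1 was 26. In the other direction, chromosome 4 from 1902586 to 1902642 held 35 and 1 reads (log2 ratio -5.71), and chromosome 15 from 99250937 to 99251000 held 276 and 155 (log2 ratio -1.42). These examples were chosen after their values were seen. By distinct fragments, the regions of chromosomes 20, 2, 4 and 15 did not pass, with 1 and 7, 1 and 12, 5 and 1, and 11 and 17 fragments (Fisher's exact test, adjusted p = 1, 0.145, 1 and 1), and on chromosome 15 the higher number was then in experiment 2. When reads with the same ends were counted once, 5 regions differed, all with a higher share in experiment 2, among them the chromosome 8 region (11 and 60 fragments, Fisher's exact test, adjusted p = 1.57e-07). All 5 were among the 19 regions of at least 50 reads in experiment 2. In them, 50.5% to 89.6% of reads had both ends within 3 nt of the most copied fragment. Their distinct fragments may thus include end variants of 1 molecule, so these p-values can also be too small.

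**Figure D2:**
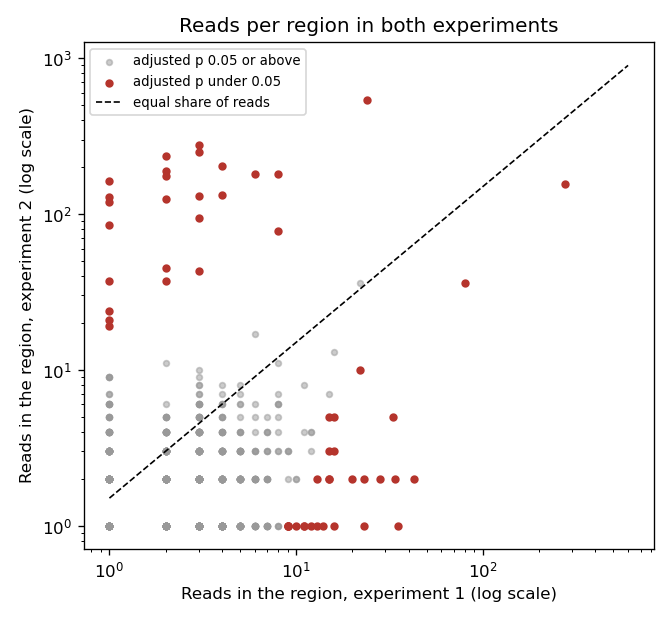
Reads per region in experiment 1 (x axis, log scale) and experiment 2 (y axis, log scale), with 1 point for each of 1181 regions. Red points are the 54 regions with an adjusted p under 0.05, and the dashed line marks equal shares of reads.

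The third question was where fragments began and ended. A fragment with the same 3' end, and a 5' end at the same base or 1 nt downstream in experiment 2, occurred in 1019 of 1181 regions (86.3%, exact interval 84.2 to 88.2). Random placement of overlapping fragments gave a mean of 14.7 regions and at most 30 in 1000 placements (one-sided permutation p = 0.001, the smallest they can give). Among 1380 pairs of distinct fragments with the same 3' end, the 5' end lay 1 nt downstream in experiment 2 in 884 pairs (64.1%) and at the same base in 227 (16.4%). It lay 2 nt downstream in 23 pairs and 1 nt upstream in 21. Within an experiment, distinct fragments with the same 3' end lay 1 nt apart in 117 of 320 pairs in experiment 1 and 63 of 161 in experiment 2. Such a pair has no direction and cannot have the same 5' end, so these counts are not directly comparable with the 64.1% between experiments. Fragments with matching ends in both experiments made up 1102 of the 1806 distinct fragments of experiment 1 and 1053 of the 1656 of experiment 2. These comparisons were chosen after the files had been examined.

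**Figure D3:**
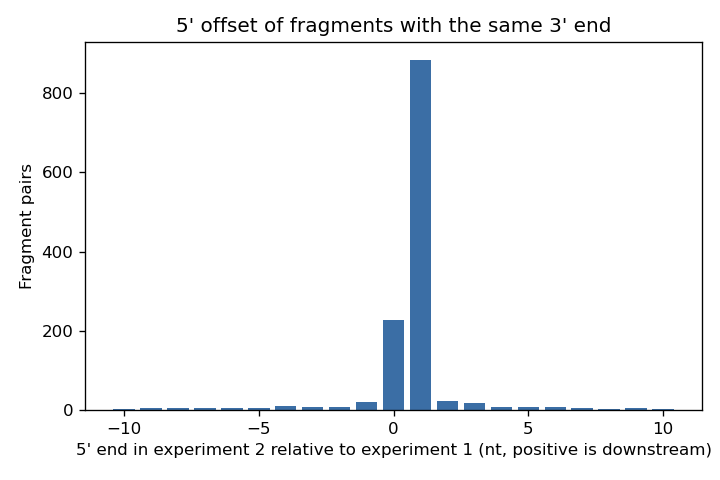
Position of the 5' end in experiment 2 relative to experiment 1 (x axis, nt, positive is downstream) for pairs of distinct fragments with the same 3' end (y axis, number of pairs). The bar at 1 nt holds 884 pairs and the bar at 0 holds 227.

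The comparison of MOV10 with control pull-down, the main question of the design, was not made, since the reads are not tied to a pull-down in the sources used here. No region is therefore described as enriched by the MOV10 antibody.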

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

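Alternatives for the reads per region, matching ends, shares of reads and chromosomes were chosen after the data were seen, as was a minimum mapping quality of 30 throughout. Over 7 results and 32 alternatives, 19 kept their direction and side of the threshold, or a count within 1.5 times. With the upper 50% of mapping quality, 722 of 1181 regions were left, and 724 shared clusters of 1186, because fewer reads were used. Without replicate 1 or 2 the list held 1186 clusters, and it could not fall below 1181, since each listed region holds reads of both experiments. All 1186 clusters were already shared, so a window of 100 nt or ignoring strand could not change that count. These alternatives are among the 19 kept but do not test stability. The correlation of reads per region fell to 0.0209 without regions of matching ends and to 0.0956 in the reads named 06, neither past the threshold, where Pearson's r of log2 reads was 0.149 (permutation p = 0.0585) and 0.191 (permutation p = 0.00066) against 0.186. These use 162 and 396 regions. Matching ends were found in 316, 403 and 326 regions in the 3 groups of read names, where fewer regions (396, 489 and 415) hold reads of both experiments. The shares there were 79.8%, 82.4% and 78.6%, against 86.3% over all reads. At offset 0 alone, matching ends were found in 223 regions. Regions of different share numbered 5 by distinct fragments (5 higher in experiment 2) and 27, 25 and 24 within the groups of read names (19, 19 and 18 higher in experiment 2), against 54 (25 higher). With totals taken without the 20 regions of at least 50 reads, which were then not tested, 14 regions differed, 7 higher in each. Of those 20 regions, 18 were higher in experiment 2, so most calls higher in experiment 1 depended on the totals. For distinct fragments the cause was not tested. No paired analysis was possible because the reads are not tied to a pull-down. Tests of transcript parts, gene overlap, gene lists, base composition, motifs and enrichment over control, with their alternatives, and random placement of regions were not run. The median of 1 or 2 reads per region limits what differences can be seen.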

Other observations

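All tests of explanations here were chosen after the results they measure had been seen. Of the distinct fragments, 53.3% in experiment 1 and 39.1% in experiment 2 occurred in at least 2 of the 3 groups of read names. In experiment 2, 1009 of 1656 fragments occurred in 1 group. The 9 regions of the chromosome 17 locus from 47128694 to 47133445 each held more reads in experiment 1, and the region from 47130426 to 47130529 in it held most, with 34 reads against 2. That direction was common, since outside the 20 regions of at least 50 reads experiment 1 held 3587 reads and experiment 2 held 2552. By distinct fragments, none of the 9 regions passed, and that with most reads held 11 against 2. Of the 1181 regions, 688 had a read of mapping quality 70 in both experiments, and 105 had none of at least 30 in either.

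Fragments with matching ends in both experiments occurred in 1019 regions, far above the highest random placement of overlapping fragments (30 regions), which argues against chance overlap. Identical sites read at identical positions would put most pairs at offset 0, where 20.4% of the pairs at offset 0 or 1 lay (exact binomial p = 5.81e-92). A 1 nt trimming difference between experiments stays open: over all pairs, offset 0 was commoner where experiment 2 had more copies (odds ratio 2.73, exact Fisher p = 1.28e-07), but error variants of a fragment can give that, and in regions with 1 fragment in each experiment, a restriction made after that value was seen, the odds ratio was 1.55 (p = 0.0958). A candidate explanation is that a cDNA was counted under both barcodes after a 1 nt slip. At offset 0, experiment 1 had the lower mapping quality in 73 pairs, the higher in 12 and the same in 142 (85.9% lower of those that differed). At offset 1 it had the lower in 23 and the higher in 243. There its fragment is 1 nt longer, so a higher mapping quality can follow from length alone and does not bear on a slip. The offset 0 count does not separate a slip from a trimming difference, whose effect on mapping quality was not tested. Shared linkage sites combined with a trimming difference also stay open, so how far the regions are independent between experiments is not settled.

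Whether variants of a few highly copied fragments account for the concentration of reads of experiment 2 in 19 regions is left open. In these regions 86.8% of reads had both ends within 3 nt of the most copied fragment (50.5% to 100% per region, lowest on chromosome 8 from 70602300 to 70602430), but in the 85 regions of experiment 2 with 5 to 49 reads the share was 87.4%, so the test does not set the 19 regions apart. Ambiguous alignment as the whole cause is argued against, since 5 of the 19 regions had a median mapping quality under 30. Those 5 include the chromosome 8 region, which held most reads (539) and had a median of 29. No biological explanation was tested, because the design names no difference between the experiments.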
